A study of Saccharomyces cerevisiae with 8 samples.

How the data were processed

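Direct RNA sequencing (DRS) on the Helicos platform reads the 3′ ends of polyadenylated RNA molecules without a cDNA step, so that each read marks a poly(A) site. It was run on total RNA from 8 yeast cultures of the W303 background, per the labels' protocols. In every strain the chromosomal PCF11 gene was replaced with TRP1 and the cells lived on a LEU2 plasmid that carried PCF11 or an allele of it. Pcf11 is an essential subunit of cleavage factor IA, the complex that cleaves pre-mRNA at the poly(A) site and helps RNA polymerase II to terminate. Wild-type cells had V5- and MYC-tagged PCF11. The pcf11-13 strain had an untagged allele, and the pcf11-dNL strain had a tagged allele whose name in the labels is deltaN-link. The pcf11-13 strain was MATa and all other strains were MATalpha, per the labels. Cultures grew in rich glucose medium at 30 °C, and the treated cultures grew for a further 2 h after 20 mM caffeine was added. Caffeine inhibits the TORC1 kinase in yeast and stresses the cell wall. Time in culture and cell density therefore differ along with caffeine.

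The samples form 6 groups. Untreated and caffeine-treated wild type had 2 libraries each, from experiments 1 and 2 in the labels. Each mutant had 1 untreated and 1 treated library, pcf11-13 in experiment 1 and pcf11-dNL in experiment 2. The labels do not say how cultures were shared between experiments beyond these numbers, so that p-values measure the spread between these samples, which may be technical.

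Per the file headers, the authors deposited 4 tables over the same 5933 genes, with 8 libraries each. The first holds expected counts, that is counts per gene that the authors estimated from the DRS reads before they deposited them, without normalization. Of these values 9.72% were whole within 1e-06, and they sum to different totals in different libraries. The second holds the authors' average 3′ UTR length per gene in nucleotides, per the file headers, with 40 values in 5 genes listed at -1, which were treated as missing. The third holds, as the deposited fraction, the share of a gene's reads that were truncated. Weighted by the counts, this fraction equalled 1 minus the authors' pooled 3′ UTR reads over all reads to within 0.00037. The last holds a deposited fraction named ProPrx in the file headers, here the proximal measure. It was no larger than the truncated fraction in 100% of values, but the bounds of the region it covers are not given in the sources used here. The build was sacCer3, per the submitters' processing notes. The aligner, the counting rules and the treatment of strand and of reads with several places are not given in the sources used here. Genes with a near-identical copy, such as many paired ribosomal protein genes, the silent mating cassettes, TDH2 and the hexose transporters, and overlapping genes are therefore uncertain. Of the gene identifiers, 5919 matched a locus tag of the RefSeq annotation of the same assembly (R64) and 14 did not. Coordinates are those of that annotation, 1-based.

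Total counts ran from 1070278 to 4555751 per library. The counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjustment, threshold 0.05). This left 5849 genes. The caffeine effect in wild type and the difference of that effect in each mutant came from a fit of 6 group means over all 8 libraries, whose residual spread comes from the wild-type pairs alone. The mutant effects and the difference between the mutants came from an additive fit of genotype and medium, in which the 2 media of a mutant are its 2 libraries. A mutant effect is thus an average over both media, and the single mutant libraries were assumed to vary like the others. A caffeine response that differs by genotype, and a difference between the experiments, add to the residual spread of this fit. Each mutant was grown in a single experiment. Without a block, a difference between the experiments therefore also enters each mutant effect in part, and the difference between the mutants in full. Levels are TMM-scaled CPM, and log2 values of single libraries used a prior count of 2. The poly(A) measures were tested with limma 3.58.1 (lmFit and eBayes, no trend) on the deposited values, with the same designs, over genes with at least 20 counts in every library: 5167 genes, of which 5165 had a length in every library. It had been planned to test the counts behind a fraction where a file gave them. The files give such counts only pooled over the libraries, so limma was kept, and an edgeR test on class counts rebuilt as fraction times count was added after seeing the data.

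Before the data were examined, 27 gene lists, the designs, most alternatives and a rule for the genes named in the text were fixed. The rule takes PCF11 and, for each expression comparison, up to 6 called genes with the largest rise and up to 6 with the largest fall among genes with a mean of at least 50 counts that moved alike in every pair of libraries of the comparison. From each list it takes 2 to 4 called members with the largest change, or, where none was called, the 2 with the highest mean count, and the text gives some or all of these. For the poly(A) measures it takes up to 5 called genes per direction and the listed genes with known internal polyadenylation. Genes named outside this rule are said to be chosen after their values were seen. The lists were tested with camera at its preset correlation between genes, beside camera with an estimated correlation and fry. The list of 46 small nucleolar RNA genes had 0 members in the tables and could not be tested.

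The experiment number pairs the libraries, because the labels state that it marks a shared experiment. As a check, the deviations of the wild-type libraries of each experiment from their group means had a correlation across genes of 0.194 between the untreated and the treated medium, and of 0.121 without URA3 and the 2-micron plasmid features. A fit with the experiment as a block was run for every test. No pair of libraries held the same values: at most 0.59% of genes had identical counts in any pair.

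Each test was run on simulated counts or values with known changes. At simulated fold changes of 2 and 4, edgeR recovered 51% and 98% of 100 changed genes at each size for caffeine in wild type, and 34% and 98% for pcf11-13. For pcf11-dNL it recovered 40% and 97%, and 18% and 93% for the difference between mutants. For the difference of the caffeine response it recovered 4% and 43% in pcf11-13, and 6% and 53% in pcf11-dNL. With nothing changed, it called 0 genes in the first 4 of these comparisons and 1 and 2 genes in the last pair. With the changed genes in place, 13, 6, 6, 11, 5 and 8 unchanged genes were called in these comparisons, in the same order. For the poly(A) measures, limma was tested on changes of 10 and 30 residual standard deviations of a gene. For length it recovered 60% and 100% for caffeine in wild type (5 false calls), 100% and 100% in pcf11-13 (24) and in pcf11-dNL (12), and 16% and 99%, and 22% and 96%, for the response differences (10 and 9). For the truncated share it recovered 54% and 100% (7 false calls), 99% and 100% (12), 100% and 100% (5), 23% and 96% (2), and 17% and 90% (3) in the same order. For the proximal measure these were 30% and 91% (6), 93% and 100% (12), 98% and 100% (13), 7% and 48% (5), and 4% and 52% (3). With nothing changed limma called 0 genes except 1 for the proximal measure in pcf11-dNL. The edgeR test of class counts was run on changes of 20 and 40 percentage points. It recovered between 47% and 61%, and 100%, for the truncated share in wild type and the mutants (8, 10 and 9 false calls), and 3% and 39%, and 0% and 31%, for the response differences (2 and 0). For the proximal measure it recovered 24% and 86%, 12% and 98%, and 19% and 97% (0, 1 and 4 false calls), and 0% and 21%, and 0% and 18%, for the response differences (0 and 0). The class counts were drawn with a preset extra spread, not one estimated from these libraries, and only genes with a mean fraction away from both ends were changed. These figures therefore do not show how the class-count test performs on the real spread. With an estimated correlation, camera recovered 0 of 10 changed lists for caffeine in wild type and for both differences of the caffeine response. With the preset correlation it recovered 10, 3 and 8. For pcf11-13, pcf11-dNL and the difference between the mutants it recovered 8, 9 and 7 with an estimated and 10, 10 and 8 with the preset correlation. Genes were drawn independently in these simulations, so the members of a list were not correlated. The simulations therefore do not show how the preset correlation performs on lists of genes that vary together. DESeq2 1.42.0, other scaling, filters, count minimums and transformations, and fits without each library in turn were run as alternatives. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.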

Results

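Poly(A)-site reads were counted in 8 libraries of budding yeast that lived on plasmid-borne PCF11, pcf11-13 or pcf11-dNL, with or without 20 mM caffeine for 2 h. Each wild-type medium had 2 libraries, 1 from each of experiments 1 and 2, and each mutant had 1 library per medium. Untreated wild type had total counts of 1070278 in experiment 1 and 1631254 in experiment 2, and treated wild type had 4413677 and 4410374. The pcf11-13 libraries had 2393801 counts untreated and 2088078 treated, and the pcf11-dNL libraries had 1071339 and 4555751. The treated library was thus 4.12, 2.70 and 4.25 times as deep as its untreated partner in wild type of experiments 1 and 2 and in pcf11-dNL, but 0.872 times as deep in pcf11-13. In both wild-type libraries of experiment 1, URA3 and the 2-micron plasmid features took 8.36% (untreated) and 11.4% (caffeine) of the counts, against 0.252% to 0.463% in the other 6 libraries.

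The targeted gene, PCF11 (YDR228C, chromosome IV, 921926 to 923806), was read from the plasmid in every strain, so that its count does not test which allele a culture held. Its level was 205 and 134 CPM (TMM-scaled) in wild type of experiment 1 without and with caffeine, and 109 and 111 in experiment 2. It was 189.5 and 222 in pcf11-13, and 133 and 110 in pcf11-dNL. PCF11 RNA did not pass the test in any comparison: the log2 change was -0.36 ± 0.31 (SE, edgeR adjusted p = 0.41) with caffeine in wild type, 0.58 ± 0.27 (0.25) in pcf11-13 and -0.19 ± 0.28 (1) in pcf11-dNL. The mating-type markers went with the labels. MFA2 (YNL145W, chromosome XIV, 352414 to 352530), which encodes a-factor, stood at 1864 and 1312 CPM in the pcf11-13 libraries and between 7.47 and 25.2 in the other 6. MF(ALPHA)1 (YPL187W, chromosome XVI, 193648 to 194145), which encodes alpha-factor, stood at 13.5 and 14.7 in pcf11-13 and between 129 and 1333 elsewhere.

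**Figure D1:**
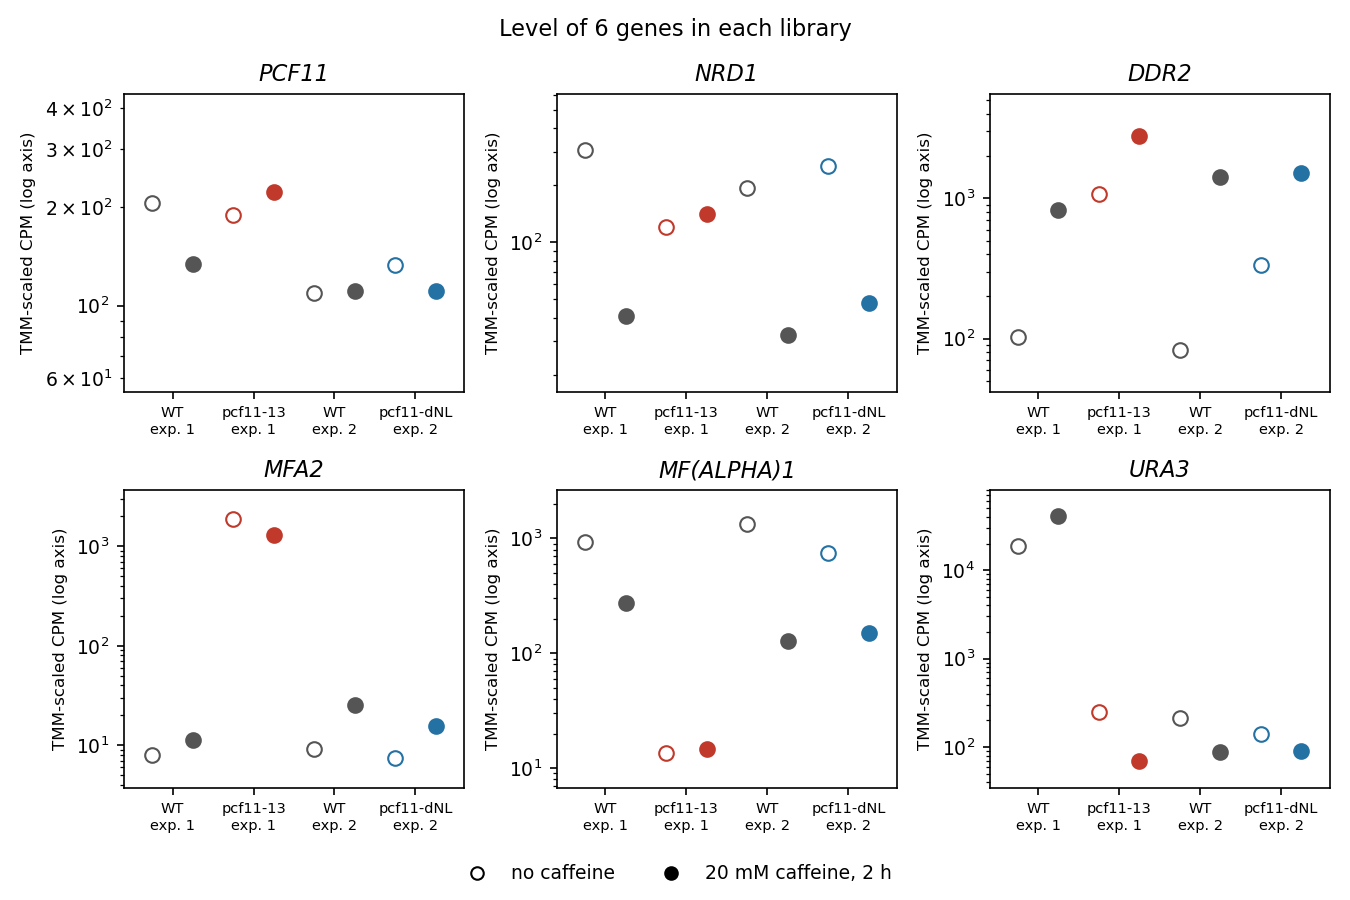
TMM-scaled CPM (log axis) of PCF11, NRD1, DDR2, MFA2, MF(ALPHA)1 and URA3 in each of the 8 libraries, with untreated libraries as open and caffeine-treated libraries as filled circles; each circle is 1 library. NRD1 fell from 306 to 40.9 and from 193 to 32.4 in the wild-type pairs and from 254 to 47.95 in pcf11-dNL, and stood at 120 and 142 in pcf11-13.

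The first comparison asked which genes 20 mM caffeine changed in wild type. The largest rises and falls came from genes of several pathways. MLS1 (YNL117W, chromosome XIV, 406358 to 408022), the malate synthase of the glyoxylate cycle, rose by 5.70 ± 0.35 on the log2 scale (SE, 2 libraries per medium), and DAK2, a dihydroxyacetone kinase, by 5.62 ± 0.74. SNO1 (5.39 ± 0.40) and SNZ1 (5.03 ± 0.43) of vitamin B6 synthesis, the allantoate permease DAL5 (5.04 ± 0.34) and the catabolic serine and threonine deaminase CHA1 (4.64 ± 0.61) rose as well. The alpha-factor gene MF(ALPHA)2 fell (-5.77 ± 0.51), as did the G1 cyclin gene PCL1 (-4.24 ± 0.40) and the histone genes HTA2 (H2A, -3.95 ± 0.31) and HTB2 (H2B, -2.91 ± 0.33). CSI2 (-3.35 ± 0.26) and the ribosomal protein gene RPL18B (-2.82 ± 0.44) fell as well. Adjusted p-values of these 12 genes ran from 0.00072 to 0.0038 in edgeR, and each moved alike in both experiments. In all, 1849 of 5849 genes passed, 1000 higher and 849 lower. An unadjusted p under 0.05 was reached by 2591 genes, where 292 would do so by chance. Without the untreated or the treated wild-type library of experiment 2, 989 and 1207 genes passed.

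Growth genes fell as groups. Of 77 ribosome biogenesis genes, 51 fell and 0 rose (62 fell when adjusted over the list alone), with a median log2 change of -1.11, and the list passed with camera (adjusted p = 1.1e-14; adjusted p = 0.55 with an estimated correlation). Among them were NOG2, a GTPase of the large subunit (-2.66 ± 0.34), and KRR1 of the small subunit processome (-2.29 ± 0.31). Of 137 cytosolic ribosomal protein genes, 33 fell and 0 rose (24 adjusted over the list alone), with a median of -0.69 (camera adjusted p = 7.6e-12; adjusted p = 0.60 with an estimated correlation). Its median was -0.26 in experiment 1 (43 genes higher) and -1.06 in experiment 2 (2 higher). RPS22B (-2.80 ± 0.38) and RPS9A (-2.66 ± 0.37) were among the called genes. Of 19 subunits of RNA polymerases I and III, which make ribosomal and transfer RNA, 8 fell (10 adjusted over the list alone; camera adjusted p = 0.00022; adjusted p = 0.55 with an estimated correlation). The medians were -0.35 and -1.30 in experiments 1 and 2. The called genes included RPA190 (-1.69 ± 0.31) and RPA49 (-1.54 ± 0.24). Of 8 histone genes, 7 fell (8 adjusted over the list alone), with a median of -2.26 (camera adjusted p = 1.2e-06; adjusted p = 0.55 with an estimated correlation). Of 12 genes of the phosphate regulon, 11 fell, also when adjusted over the list alone, with a median of -1.66 (camera adjusted p = 1.2e-05; adjusted p = 0.55 with an estimated correlation). The phosphate transporter gene PHO84 (-2.70 ± 0.38) and SPL2 (-2.07 ± 0.28) led.

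Stress and nitrogen genes rose as groups. Of 56 genes of the induced environmental stress response, 33 rose and 1 fell (34 and 1 adjusted over the list alone), with a median of 1.26 (camera adjusted p = 2.7e-09; adjusted p = 0.55 with an estimated correlation). DDR2, a stress-induced gene, rose by 3.59 ± 0.44. HSP26, a small chaperone, rose by 4.62 ± 0.82, and by 2.81 without the treated wild-type library of experiment 2. Of 24 Hsf1 heat shock targets, 14 rose and 0 fell, and the same count held when adjusted over the list alone (median 1.31; camera adjusted p = 4.8e-05; adjusted p = 0.57 with an estimated correlation). HSP82, which encodes Hsp90, rose by 3.20 ± 0.59. Of 21 genes under nitrogen catabolite repression, 15 rose and 1 fell, both also when adjusted over the list alone (median 2.16; camera adjusted p = 1.2e-05; adjusted p = 0.55 with an estimated correlation). CPS1, a vacuolar carboxypeptidase, rose by 3.36 ± 0.36. Of 13 purine synthesis genes, 8 rose and 2 fell (9 and 3 adjusted over the list alone; median 1.30; camera adjusted p = 0.01; adjusted p = 0.55 with an estimated correlation). SHM2, a serine hydroxymethyltransferase, rose by 4.05 ± 0.44 and ADE17 by 3.44 ± 0.40. Of 11 autophagy genes, 7 rose (8 adjusted over the list alone), among them ATG33 (1.82 ± 0.33) and ATG34 (1.72 ± 0.27; list median 1.22; camera adjusted p = 0.00041; adjusted p = 0.55 with an estimated correlation).

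Smaller lists also passed with camera. Of 14 Yap1 oxidative stress targets, 7 rose, also when adjusted over the list alone, with the sulfiredoxin gene SRX1 at 3.04 ± 0.29 and the peroxiredoxin gene TSA1 at 1.89 ± 0.28 (camera adjusted p = 0.00059; adjusted p = 0.55 with an estimated correlation). Of 15 genes of the iron regulon, 5 rose, also when adjusted over the list alone, such as FIT2 at 1.60 ± 0.24 (camera adjusted p = 0.016; adjusted p = 0.55 with an estimated correlation). Of 33 proteasome genes, 8 fell and 1 rose (7 and 1 adjusted over the list alone), and RPT6 fell by 1.22 ± 0.24 (camera adjusted p = 0.0042; adjusted p = 0.55 with an estimated correlation). Of 16 glycolysis and fermentation genes, 3 fell (2 adjusted over the list alone), including TDH2 (-2.04 ± 0.45) and TPI1 (-2.16 ± 0.59; camera adjusted p = 0.0044; adjusted p = 0.55 with an estimated correlation). Of 28 factors of mRNA 3′ end processing and termination, 7 fell and 2 rose, also when adjusted over the list alone (median -0.28; camera adjusted p = 0.039; adjusted p = 0.55 with an estimated correlation). The largest fall was that of NRD1, the RNA-binding factor that terminates short non-coding transcripts and limits its own mRNA by early termination, at -2.76 ± 0.29. PAB1, the poly(A)-binding protein gene, fell by 1.11 ± 0.26. Of 5 MATalpha-specific genes, 4 fell, also when adjusted over the list alone, including MF(ALPHA)1 (-2.49 ± 0.41; camera adjusted p = 0.01; adjusted p = 0.55 with an estimated correlation). Without the treated wild-type library of experiment 2 the changes of PAB1 (-0.91, edgeR adjusted p = 0.138), RPT6 (-1.14, 0.0559) and TPI1 (-2.18, 0.0929) missed the threshold. TPI1 also missed it without either untreated wild-type library (-2.05 and -2.26).

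The other lists did not pass with camera for caffeine in wild type. Cell wall integrity genes went both ways, 5 of 17 higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 0.10). The wall protein genes PST1 (3.04 ± 0.44) and PIR3 (2.72 ± 0.32) rose and CIS3 (-2.11 ± 0.29) fell. Of 38 Gcn4 targets of amino acid synthesis, 7 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.70), with HIS5 at 2.06 ± 0.31, ARG4 at 2.30 ± 0.42 and ARO4 at -1.91 ± 0.41. ARG4 missed the threshold without the untreated library of experiment 2 (2.06, edgeR adjusted p = 0.0545). Of 14 sulfur amino acid genes, 5 rose and 1 fell (6 and 3 adjusted over the list alone; 0.58), led by the sulfate permease gene SUL1 (2.19 ± 0.25) and MET28 (1.71 ± 0.31). Of 11 genes with known premature or internal polyadenylation, 2 rose and 3 fell, also when adjusted over the list alone (0.27). ADE12 rose by 1.46 ± 0.25, and DEF1, which acts in the degradation of stalled RNA polymerase II, fell by 1.91 ± 0.30. Of 10 hexose transporter genes, HXT5 rose (3.17 ± 0.53) and HXT1 fell (-2.40 ± 0.72; 1 and 0 adjusted over the list alone; 0.71). The HXT1 call was lost without the untreated library of experiment 2 (-0.29) and with the experiment as a block (-1.85, edgeR adjusted p = 0.0597). The list's median was 0.78 in experiment 1 and -2.27 in experiment 2. Pleiotropic drug resistance had 4 of 10 higher and 1 lower (0.30), with PDR10 at 2.29 ± 0.35. Ergosterol synthesis had 5 of 20 higher and 1 lower (median -0.05, mean 0.11; 0.82), with ERG7 at 1.35 ± 0.32 and ERG28 at -1.29 ± 0.28. The respiratory chain had 3 of 33 higher and 4 lower (median 0.05, camera direction down; 0.93), with COX6 at 1.29 ± 0.28. Pheromone response had 2 of 12 higher, PRM2 (2.18 ± 0.32) and PRM1 (1.91 ± 0.30), and 2 lower (0.71). These counts of the last 4 lists were equal when adjusted over the list alone. Of 7 MATa-specific genes, STE6 was higher (0.94 ± 0.26) and AGA2 lower (-1.23 ± 0.39), also adjusted over the list alone (0.18). AGA2 missed the threshold without any 1 of the 4 wild-type libraries (-1.05 to -1.36), and STE6 without the untreated or the treated library of experiment 2 (0.72 and 0.90).

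**Figure D2:**
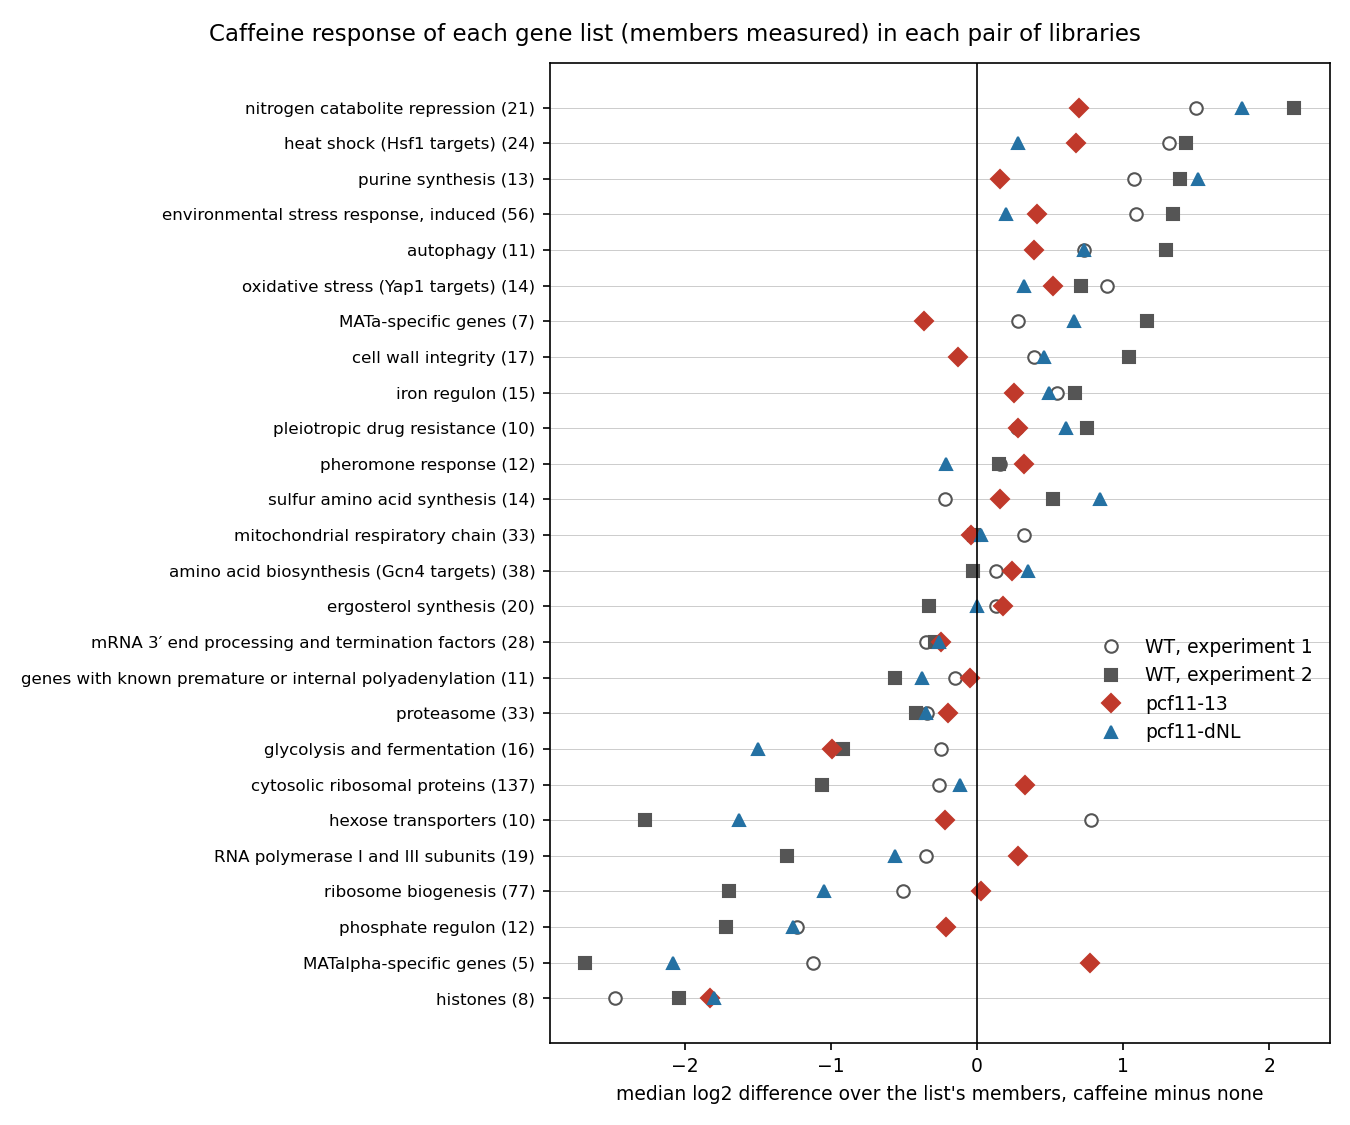
Median log2 difference between the treated and the untreated library over the measured members of each gene list, in wild type of experiment 1 (open circles), wild type of experiment 2 (squares), pcf11-13 (diamonds) and pcf11-dNL (triangles). Ribosome biogenesis stood at -0.51, -1.70, 0.03 and -1.05 in these 4 pairs, and the induced stress response at 1.09, 1.34, 0.41 and 0.20.

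The next comparison set pcf11-13 against wild type, over both media. The largest changes were those of mating type, which differs between these strains in the labels. All 7 MATa-specific genes rose, also when adjusted over the list alone (median 3.43; camera adjusted p = 7.7e-13; adjusted p = 0.16 with an estimated correlation; fry adjusted p = 0.002). The a-factor genes MFA2 (6.95 ± 0.45) and MFA1 (4.25 ± 0.34), the a-agglutinin gene AGA2 (3.74 ± 0.26) and the alpha-factor receptor gene STE2 (3.43 ± 0.22) led, with edgeR adjusted p from 0.00023 to 7e-04. Of 5 MATalpha-specific genes, 3 fell, also when adjusted over the list alone, led by MF(ALPHA)1 (-4.95 ± 0.70) and the a-factor receptor gene STE3 (-3.24 ± 0.68; camera adjusted p = 0.00047; adjusted p = 0.73 with an estimated correlation). Outside mating type, the peroxisomal thiolase gene POT1 (3.27 ± 0.30) and the uncharacterised YCR101C (2.73 ± 0.47) rose most. PTC2 (-1.88 ± 0.35), CIN4 (-1.77 ± 0.31), VAN1 (-1.76 ± 0.38) and ZIM17 (-1.66 ± 0.34) fell most. In all, 181 genes passed, 143 higher and 38 lower, and 1231 reached an unadjusted p under 0.05.

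Of the 56 stress-response genes, 8 rose in pcf11-13 (16, and 1 lower, adjusted over the list alone; median 0.54; camera adjusted p = 8.9e-08; adjusted p = 0.89 with an estimated correlation), with DDR2 at 2.48 ± 0.49 and the stress repressor gene XBP1 at 1.87 ± 0.33. The cytosolic ribosomal protein list was lower with camera (median -0.44, adjusted p = 3.4e-11; adjusted p = 0.89 with an estimated correlation), with 0 of 137 genes called by edgeR, also adjusted over the list alone. RPL39 was at -0.55 ± 0.41 and RPL28 at -0.54 ± 0.36. Lists also passed with camera for pheromone response (median 0.35, adjusted p = 0.028; adjusted p = 0.65 with an estimated correlation), where PRM3 rose (1.37 ± 0.22; 4 genes adjusted over the list alone). Ergosterol synthesis was lower (-0.36, adjusted p = 0.0027; adjusted p = 0.80 with an estimated correlation) and the hexose transporters higher (0.67, adjusted p = 0.023; adjusted p = 0.80 with an estimated correlation), each with 0 genes called by edgeR. Cell wall integrity was higher (0.36, camera adjusted p = 0.016; adjusted p = 0.89 with an estimated correlation) but lost the call with the experiment as a block (0.28), while the Gcn4 targets gained it (0.28 without and 0.028 with the block; adjusted p = 0.89 with an estimated correlation and no block). The other 18 tested lists did not pass with camera. Single members of these that passed were SUL1 (1.42 ± 0.26), SYC1 of the cleavage and polyadenylation factor (-1.23 ± 0.27), SUA7, which encodes TFIIB (-1.09 ± 0.22), the proteasome gene PRE10 (-1.15 ± 0.23) and SDH1, which encodes a subunit of succinate dehydrogenase (1.14 ± 0.25, edgeR adjusted p = 0.05). Within experiment 1, the medians without and with caffeine were 1.17 and 0.50 for the stress response, -0.79 and -0.23 for ribosomal proteins, and 0.42 and 0.58 for pheromone response. They were -0.04 and -0.36 for ergosterol synthesis, 1.12 and 0.80 for the hexose transporters, and 0.39 and -0.11 for cell wall integrity.

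How many genes passed for pcf11-13 depended on the libraries in the fit. With the experiment as a block, 30 genes passed (18 higher, 12 lower), 20 of them among the 181. Only 30, 49, 23 and 57 passed without the untreated or treated wild-type library of experiment 1 or those of experiment 2, in that order, and 52 and 43 without the untreated or treated pcf11-dNL library. Of the 20 called genes named here, MFA2, MFA1, AGA2, STE2, POT1 and MF(ALPHA)1 kept their call without any 1 library, and the other 14 lost it without at least 1. Without the untreated pcf11-13 library, DDR2 was at 1.52, SUL1 at 0.90, STE3 at -2.12 and ZIM17 at -2.49. Without the treated one, SDH1 was at 0.62, STE3 at -4.92, PTC2 at -1.22 and ZIM17 at -1.10.

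The pcf11-dNL strain was compared with wild type in the same way. Stress genes leaned higher and ribosomal protein genes lower as lists, with no single gene past the threshold. The induced stress response had a median of 0.49 over its 56 genes (camera adjusted p = 1.4e-23; adjusted p = 0.83 with an estimated correlation), and cytosolic ribosomal proteins of -0.47 over 137 genes (camera adjusted p = 2e-29; adjusted p = 0.83 with an estimated correlation). Without caffeine, within experiment 2, these medians were 0.98 and -0.89, and with caffeine -0.05 and 0.11. DDR2 was at 1.06 ± 0.48, RPL39 at -0.44 ± 0.40 and RPL28 at -0.51 ± 0.35 over both media. Ribosome biogenesis was lower (-0.27; camera adjusted p = 2.6e-05; adjusted p = 0.83 with an estimated correlation), with NOP1 at -0.38 ± 0.39. Gcn4 targets (-0.19; camera adjusted p = 0.00034) and heat shock targets (0.30; 0.0019), with HSP82 at 0.90 ± 0.56, passed too (adjusted p = 0.83 with an estimated correlation). With the experiment as a block they did not (0.19 and 0.55), and the direction of the heat shock list turned from higher to lower. With the block the respiratory chain (0.016), phosphate (0.016) and ergosterol (0.0026) lists were lower, of which the respiratory chain had leaned higher without it (camera adjusted p = 0.16). Without the block the medians of these 3 lists were 0.12, -0.27 and -0.12, and camera with an estimated correlation gave them an adjusted p = 0.86, an adjusted p = 0.84 and an adjusted p = 0.83. By edgeR 0 genes passed, also within each list alone, and 163 reached an unadjusted p under 0.05 (131 higher, 32 lower), where 292 would by chance. Caffeine responses that differ between strains add to the residual spread of this fit. The count therefore does not show the absence of an effect. DESeq2 called 0 genes too, and 1 gene passed without the treated pcf11-dNL library.

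Set against each other, the mutants differed in mating-type genes. Without a block this comparison also holds the difference between the experiments. MFA2 was lower in pcf11-dNL than in pcf11-13 by -7.15 ± 0.61 on the log2 scale, MFA1 by -4.13 ± 0.44, STE2 by -3.28 ± 0.29 and AGA2 by -3.20 ± 0.32, with edgeR adjusted p from 0.003 to 0.0082. These 4 genes were all that passed by edgeR, with 727 at an unadjusted p under 0.05, while DESeq2 called more, as given below. Of the 7 MATa-specific genes 4 were lower, and all 7 when adjusted over the list alone (median -3.20; camera adjusted p = 3.4e-15; adjusted p = 0.12 with an estimated correlation; fry adjusted p = 0.0046). The MATalpha-specific list was higher (1.86; camera adjusted p = 0.00032; adjusted p = 0.95 with an estimated correlation), with 3 of 5 genes adjusted over the list alone. Heat shock (0.57; camera adjusted p = 0.00015; 1 gene adjusted over the list alone), cell wall integrity (-0.48; 0.0022), respiratory chain (0.25; 0.016) and ergosterol (0.35; 0.037) lists also differed (each adjusted p = 0.95 with an estimated correlation). These 4 did not with the experiment as a block (0.66, 0.67, 0.20 and 0.80), and heat shock and the respiratory chain turned from higher to lower in pcf11-dNL, while the stress response (0.0076), the hexose transporters (0.032) and pheromone response (0.044) were lower in pcf11-dNL. Without the block the medians of these 3 lists were 0, -0.31 and -0.08, and camera with an estimated correlation gave them an adjusted p = 1, an adjusted p = 0.95 and an adjusted p = 0.95. The block gave 8 genes, and AGA2 then missed the threshold (-3.46, edgeR adjusted p = 0.0874). Without either pcf11-dNL library 0 genes passed by edgeR, and 61 and 34 passed without the untreated or the treated pcf11-13 library. PCF11 was at -0.78 ± 0.32 (edgeR adjusted p = 0.37).

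The caffeine response itself was then compared between strains. In pcf11-13 it was smaller. Over the 1000 genes that rose in wild type, the median log2 rise was 1.16 and 1.38 in the wild-type pairs, 1.22 in pcf11-dNL and 0.48 in pcf11-13. Over the 849 genes that fell it was -0.95, -1.35, -1.11 and -0.41. Those genes were chosen on the wild-type pairs, so the 500 largest rises of wild type in experiment 2 were also followed in the other pairs. Their medians were 1.50 in wild type of experiment 1, 1.66 in pcf11-dNL and 0.73 in pcf11-13. The 500 largest falls had medians of -1.0, -1.35 and -0.34. Untreated pcf11-13 already stood above untreated wild type of experiment 1 in the 500 rising genes, by 0.61 (95% bootstrap interval over genes 0.54 to 0.68), and below it in the 500 falling genes, by -0.45 (-0.50 to -0.41). With caffeine, pcf11-13 stood at -0.23 (-0.30 to -0.12) and 0.23 (0.18 to 0.29). These were single libraries and the intervals were over genes. Untreated pcf11-dNL stood above its own control as well, by 0.21 over the 1000 raised genes, with 68.6% of them above. Those genes were chosen in part on that same control library, which favours a positive value. Across genes, this difference correlated at 0.419 with caffeine in wild type of experiment 2, which shares that library. With experiment 1, which shares none, the correlation was 0.177.

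**Figure D3:**
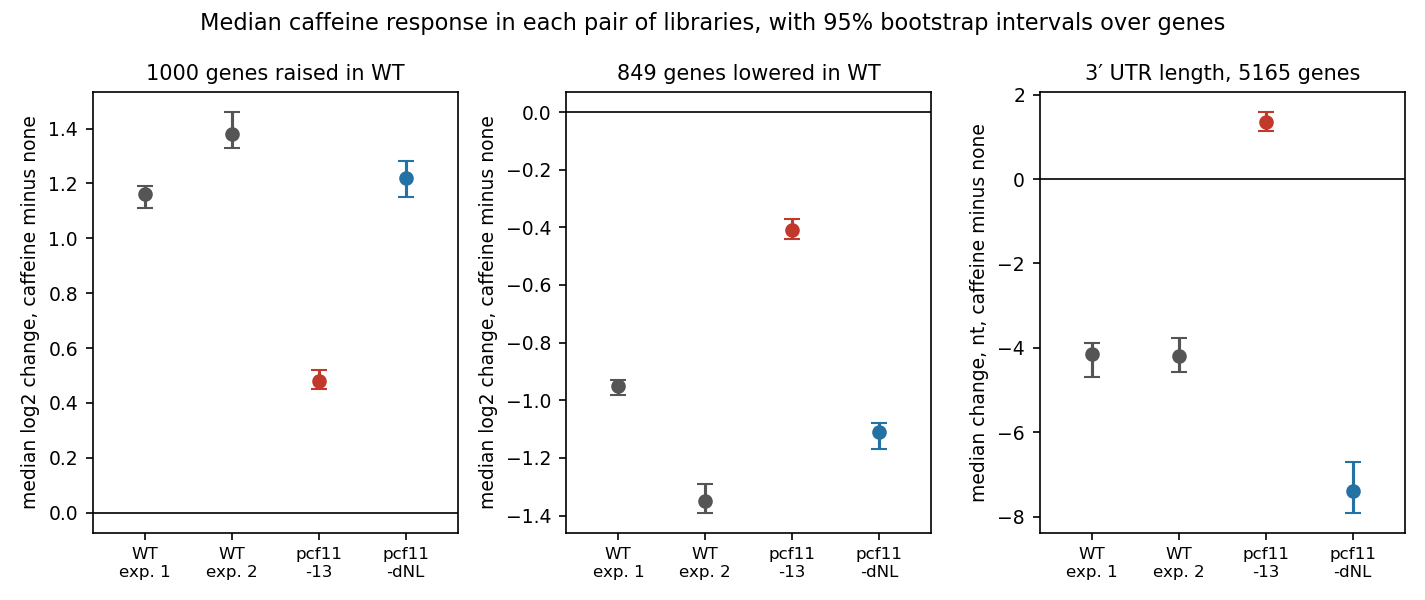
Median difference between the treated and the untreated library in each of the 4 pairs, over the 1000 genes raised and the 849 genes lowered by caffeine in wild type (log2) and for the average 3′ UTR length of 5165 genes (nt); bars are 95% bootstrap intervals over genes, and the axes are linear. The pcf11-13 pair stands apart in each panel, at 0.48, -0.41 and 1.35 nt.

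As lists, the caffeine responses of growth genes were higher in pcf11-13 than in wild type. The difference of the responses had a median of 1.24 over ribosome biogenesis (camera adjusted p = 2.3e-20), 0.95 over ribosomal proteins (3.9e-25), 1.03 over polymerase I and III subunits (6.7e-06) and 1.25 over the phosphate regulon (1.4e-05). With an estimated correlation each of these 4 lists had an adjusted p = 0.66. Within the pcf11-13 pair, the treated library stood above the untreated one by a median of 0.33 over ribosomal proteins (111 of 137 genes higher), 0.28 over polymerase I and III subunits and 0.03 over ribosome biogenesis. In wild type of experiment 1, the experiment of pcf11-13, these medians were -0.26, -0.35 and -0.51. In wild type of experiment 2 they were -1.06, -1.30 and -1.70. The differences above use the mean of both, so part of their size comes from experiment 2. NOP1, the small nucleolar RNA methyltransferase gene, differed by 1.64 ± 0.58 and RLP7 by 1.55 ± 0.55, neither past the threshold (both edgeR adjusted p = 0.29). The response was lower for the stress response (-0.84; camera adjusted p = 5.7e-06), nitrogen catabolite repression (-1.01; 0.00013), autophagy (-0.83; 0.0018), cell wall integrity (-0.79; 0.0048) and purine synthesis (-1.04; 0.017), and higher for MATalpha-specific genes (2.61; 2.7e-05) and histones (0.60; 0.017). These lists had an adjusted p = 0.66 or an adjusted p = 0.67 with an estimated correlation. The MATalpha-specific genes were already low in untreated pcf11-13, which is MATa, so their difference goes with mating type. SHM2 of purine synthesis differed by -2.42 ± 0.69 (edgeR adjusted p = 0.26). Heat shock passed only with the experiment as a block (0.11 without, 0.01 with it; adjusted p = 0.80 with an estimated correlation and no block). Within lists that passed with camera, and adjusted over the list alone, 5 purine, 3 nitrogen, 2 stress-response and 1 cell wall genes were lower. In the same way, 4 MATalpha-specific genes and 1 histone gene were higher.

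Gene by gene, edgeR called 0 differences of the caffeine response in pcf11-13, with 826 genes at an unadjusted p under 0.05 (292 by chance) and 42 called by DESeq2. Without the treated wild-type library of experiment 1 or 2, 177 and 71 genes passed. NRD1 (YNL251C, chromosome XIV, 172588 to 174315) was among the largest differences, at 3.00 ± 0.49 (edgeR adjusted p = 0.158), and was singled out after its values were seen. In pcf11-dNL, edgeR called 0 genes too, with 128 at an unadjusted p under 0.05 and 3 called by DESeq2, and 13 and 3 passed without the treated wild-type library of experiment 1 or 2. As lists, the pcf11-dNL response differed for the stress response (median -0.95; camera adjusted p = 1.7e-23), heat shock targets (-0.81; 4.5e-08), glycolysis (-0.72; 8.1e-08), ribosomal proteins (0.56; 3.2e-22), Gcn4 targets (0.26; 0.00025), sulfur amino acid synthesis (0.26; 0.0062) and histones (0.25; 0.023). Each had an adjusted p = 0.97 with an estimated correlation. DDR2 differed by -1.41 ± 0.69 (edgeR adjusted p = 1).

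The mutant effects were set beside the caffeine effect across genes, which are not independent replicates. Pairs of libraries that shared no library gave a Pearson r of 0.799 between the 2 wild-type caffeine responses, 0.861 between wild type of experiment 2 and pcf11-dNL, and 0.600 and 0.482 between pcf11-13 and wild type of experiments 1 and 2. Spearman's rho was 0.772, 0.838, 0.525 and 0.405. Untreated pcf11-13 against its own control correlated with the caffeine response of wild type in experiment 2 at 0.441 (rho 0.470), and with untreated pcf11-dNL against its own control at 0.362 (rho 0.352). Treated pcf11-13 against its own treated control correlated with the same caffeine response at -0.14 (rho -0.183). With all controls shared, the pcf11-13 and pcf11-dNL effects correlated at 0.455, where unchanged groups simulated against the same controls gave 0.331, and their covariance was 0.0774 against 0.0343. The pcf11-13 effect correlated with caffeine in wild type at 0.212 (simulated 0.0767; covariance 0.109 against 0.00912), and the pcf11-dNL effect at 0.268 (simulated 0.0734; covariance 0.0787 against 0.0089). The simulation drew every library from the untreated wild-type mean, with genes independent and no difference between experiments. Real genes vary together between libraries, so an excess over the simulated values does not by itself show a shared effect. Of the 143 genes higher in pcf11-13, 53 rose with caffeine in wild type (24.4 for independent lists) and 8 fell (20.8). Of the 38 lower genes, 11 fell (5.52) and 3 rose (6.5). Part of the excess may come from the shared controls.

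Poly(A) site choice was described first by library. The median over 5165 genes of the average 3′ UTR length was 143 and 133 nt without and with caffeine in wild type of experiment 1, 141 and 132 nt in experiment 2, 149 and 134 nt in pcf11-dNL, and 142 and 143 nt in pcf11-13. Gene by gene, the median change with caffeine was -4.14 and -4.19 nt in wild type, with 66.6% and 67.2% of genes shorter, and -7.39 nt in pcf11-dNL with 73.1% shorter. In pcf11-13 it was 1.35 nt, with 41.4% shorter. Among genes with no more raw counts after caffeine the changes were smaller: 0.139 nt (52 genes) and -1.35 nt (356 genes) in wild type and -0.883 nt (76 genes) in pcf11-dNL. Over 301 genes with no more counts after caffeine in wild type of experiment 2 nor in pcf11-13, the medians of these pairs were -1.22 nt (95% bootstrap interval over genes -2.27 to -0.705) and 1.71 nt (1.14 to 2.8). Over 82 genes with at least 1000 counts in every library they were -3.46 nt (-5.28 to -2.29) and 0.526 nt (-0.36 to 1.1). Against wild type of its own experiment, pcf11-13 differed by 0.589 nt without and by 5.76 nt with caffeine, and pcf11-dNL by 3.6 and 0.708 nt. The wild-type libraries of the 2 experiments differed by 0.127 nt untreated and by 0.461 nt treated. The median truncated share went with caffeine from 8.73% to 5.30% and from 6.02% to 4.57% in wild type, from 8.53% to 5.35% in pcf11-13 and from 7.98% to 6.16% in pcf11-dNL. Among 52, 357 and 77 genes with no more raw counts after caffeine, its median change went the other way, by 1.25 and 1.37 points in wild type (34.6% and 15.4% of genes lower) and by 1.12 points in pcf11-dNL. In pcf11-13 it was -1.54 points over 3559 such genes (68.8% lower). The median proximal measure was between 0.343% and 0.527% in every library.

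Caffeine in wild type shortened the 3′ UTR of TRE2, which encodes a transferrin-receptor-like protein (YOR256C, chromosome XV, 808254 to 810683), by -299 ± 5.1 nt (limma adjusted p = 0.027). Its length went from 471 and 468 nt to 176 and 165 nt, and from 473 to 180 nt in pcf11-dNL. TRE2 was shorter with caffeine in pcf11-13 as well. STB5, a transcription factor gene, changed by -158 ± 2.8 nt (limma adjusted p = 0.027), on as few as 38.8 counts in 1 library. These 2 genes passed of 5165, with 1223 at an unadjusted p under 0.05 (266 longer, 957 shorter, 258 by chance). For the truncated share, limma called 0 genes, with 1021 at an unadjusted p under 0.05 (280 higher, 741 lower), and an edgeR test of class counts called 657. DEF1 had one of the larger differences of the listed genes, -36.9 ± 5.3 points (limma adjusted p = 0.13), from 55.8% and 66.4% to 20.8% and 27.6%. The proximal measure passed for RPN4, the regulator of proteasome genes (-12.5 ± 0.092 points), PBI1 (-4.40 ± 0.041) and DPH2 of diphthamide synthesis (3.66 ± 0.031; each limma adjusted p = 0.025). All of these limma calls were lost with the experiment as a block (0 genes for length and 0 for the proximal measure) and without any 1 of the 4 wild-type libraries (0 genes).

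In pcf11-13, 35 genes passed for 3′ UTR length, 23 longer and 12 shorter. MTC4 (YBR255W, chromosome II, 724456 to 726540) was longer by 457 ± 40 nt, ERP4 of the p24 family by 212 ± 24 nt, VPS41 of vacuolar fusion by 178 ± 11 nt and ORM1, a regulator of sphingolipid synthesis, by 129 ± 8 nt (limma adjusted p from 0.018 to 0.044). HMRA1 (YCR097W, chromosome III, 293835 to 294321) was shorter by -711 ± 58 nt, from 583 to 874 nt in the other 6 libraries to 60.7 and 72.3 nt, and BAR1, the MATa-specific protease gene, by -351 ± 32 nt. ATO2 (-268 ± 21 nt), YAL063C-A (-94 ± 10 nt) and the wall sensor gene WSC3 (-84.2 ± 4.8 nt) were shorter as well. HMLALPHA1 was longer by 143 ± 16 nt. HMRA1 and HMLALPHA1 are silent cassettes with near-identical copies at the mating-type locus, so reads could belong to either place, and BAR1 had as few as 28.4 counts. HMRA1 stood at 289 and 199 CPM in pcf11-13, the only MATa strain, and between 23.5 and 59.5 in the other 6 libraries. The length changes of HMRA1, HMLALPHA1 and BAR1 therefore cannot be told apart from an effect of mating type. An unadjusted p under 0.05 was reached by 1034 genes, 809 longer and 225 shorter. With the experiment as a block 8 genes passed, VPS41, ORM1 and WSC3 among them. By limma, 240 genes passed without the untreated pcf11-13 library and 0 without the treated one. Without the untreated wild-type libraries of experiments 1 and 2, 3 and 1 passed, and 0 without any 1 of the treated wild-type or the pcf11-dNL libraries.

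The truncated share passed for 11 genes in pcf11-13, 10 higher and 1 lower. POL12, a subunit gene of DNA polymerase alpha, rose by 30.9 ± 2.2 points, from 49.8% to 72.0% in the other libraries to 90.4% and 83.9%. The photolyase gene PHR1 rose by 30.0 ± 2.1 points, CVM1 by 23.4 ± 2.0, VID22 by 22.3 ± 1.9 and YFT2 by 21.4 ± 1.4, while RSF1 fell by 38.5 ± 1.6 points (limma adjusted p from 0.015 to 0.046). The proximal measure passed for 9 genes, 8 higher and 1 lower. DRN1 rose by 17.8 ± 1.3 points, COG6 of the Golgi by 14.7 ± 0.68, the fluoride exporter gene FEX1 by 12.1 ± 0.78, MRL1 by 3.92 ± 0.20 and YTH1, a subunit gene of the cleavage and polyadenylation factor, by 4.74 ± 0.32. PBI1 fell by 4.49 ± 0.15 points (limma adjusted p from 0.0089 to 0.044). With the experiment as a block 0 genes passed in either measure, and the edgeR test of class counts called 161 and 29. At an unadjusted p under 0.05 stood 750 and 472 genes. For the truncated share, between 0 and 3 genes passed without any 1 of the 8 libraries, and for the proximal measure 70 and 56 passed without the untreated or the treated pcf11-13 library and 0 without any 1 of the wild-type libraries.

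**Figure D4:**
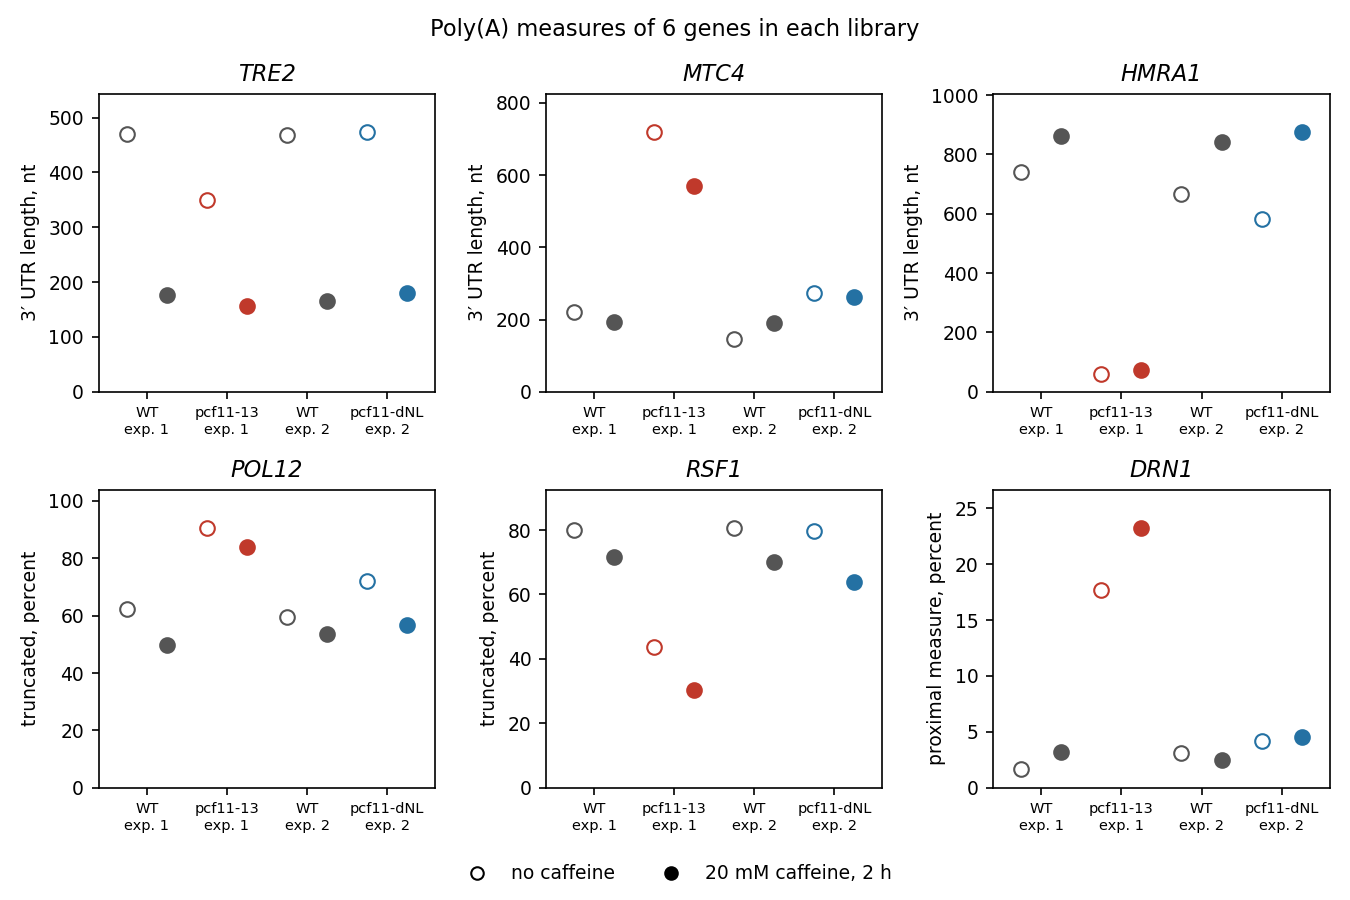
Average 3′ UTR length (nt) of TRE2, MTC4 and HMRA1, truncated share (percent) of POL12 and RSF1 and proximal measure (percent) of DRN1 in each of the 8 libraries; each circle is 1 library, open without and filled with caffeine. TRE2 falls to between 157 and 180 nt with caffeine in every pair, while the other 5 genes stand apart in both pcf11-13 libraries. For HMRA1 this cannot be told apart from mating type, since only pcf11-13 was MATa.

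In pcf11-dNL, limma called 0 genes for length, truncated share and proximal measure, with 199, 220 and 232 genes at an unadjusted p under 0.05 (258 by chance in each), most of them longer or higher (168, 209 and 209). Here too, the residual spread holds caffeine responses that differ between strains. The edgeR test of class counts called 0 and 0 genes for the 2 fractions. For the proximal measure 142 and 3 genes passed without the treated or the untreated pcf11-dNL library, and for length 2 without the treated one. Tests of whether the poly(A) response to caffeine differed between strains called 0 genes by limma for length in pcf11-13 (683 at an unadjusted p under 0.05, 554 of them longer) and 0 in pcf11-dNL (364, 289 of them shorter). The median difference of the length response was 6.25 nt in pcf11-13 and -2.48 nt in pcf11-dNL. For the truncated share limma called 0 and 0 genes (412 and 283 unadjusted). For the proximal measure limma called 1 gene, DPH2 (-12.9 ± 0.054 points, adjusted p = 0.011), in pcf11-13 and 122 in pcf11-dNL. These counts were 0 and 0 with the experiment as a block, 0 and 0 without any 1 of the 4 wild-type libraries, and 0 and 0 with the edgeR test of class counts.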

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

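All tests of explanations in this part were chosen after the results were seen. In the caffeine response, 11 gene lists in pcf11-13 and 7 gene lists in pcf11-dNL responded differently from wild type by camera at its preset correlation, but 0 and 0 lists passed with an estimated correlation (adjusted p = 0.66 or 0.67 for the 11, adjusted p = 0.97 for the 7), and 1 of the 11, the MATalpha-specific genes, goes with mating type. Over the 1000 genes raised in wild type the pcf11-13 median was 0.48 against 1.16 and 1.38 in wild type. With all libraries thinned to the smallest total it was 0.49 against 1.13 and 1.36. This argued against low counts alone as the cause. A bias in reads or counting that goes with depth would survive thinning and was not tested. Mixing of treated into untreated pcf11-13 RNA was not decided. The implied share of treated RNA was computed with treated wild type of experiment 1 as its source. Over 22 strongly raised genes the upper quartile of that share, 0.402, was 10.6 times the lower, 0.0379. Treated pcf11-13 itself differed from that library, as in DDR2 (2800 against 821 CPM) and VBA1 (477 against 1670). Unequal shares therefore do not test such mixing. A lower effective dose as the whole cause cannot be told apart from an effect of the allele: over the 500 genes raised most in pcf11-dNL untreated pcf11-13 stood at least 0.51 above either untreated wild-type library, which differed by 0.20, but over the 500 lowered most it stood at -0.34 against wild type of experiment 1, where the wild-type libraries differed by -0.31. The pcf11-13 allele may change the response, but mating type, strain background or the missing tag cannot be told apart from it. Only this strain was MATa and had an untagged allele, and all 7 MATa-specific genes were higher in it.

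In the 3′ UTR lengths, both wild-type pairs and pcf11-dNL shortened with caffeine while the median of pcf11-13 went the other way, by 1.35 nt (95% bootstrap interval over genes 1.13 to 1.59), a difference of medians that was not tested. The response was not reversed gene by gene. Over 2272 genes with at least 100 counts in every library, length changes in pcf11-13 had a Pearson r of 0.439 and 0.451 with wild type of experiments 1 and 2. With pcf11-dNL it was 0.462, and between the wild-type pairs 0.761. Over 171 genes whose count ratio with caffeine in wild type of experiment 2 was within 0.25 (log2) of that in pcf11-13, the medians were -2.52 nt (-3.61 to -1.36) and 0.639 nt (0.0242 to 1.46). Over 393 genes within 0.5 they were -3.01 and 0.639 nt. This argues against the counts per gene as the whole cause in that pair. Each pair is a single treated and a single untreated library, however, and the intervals are over genes. The 171 genes had a median count ratio of 1.04 in wild type of experiment 2, against 2.87 over all genes, so they also differ in expression. A bias that goes with the depth of the whole library would survive this match. It was not tested and stays open in that pair. Depth as the whole cause cannot be told apart from an effect of caffeine where too few genes match, in wild type of experiment 1 (-1.13 nt over 11 and -7.07 nt over 27 genes within 0.25 and 0.5; 0.139 nt over 52 genes with no more counts after caffeine; -2.83 nt over 82 genes with at least 1000 counts) and in pcf11-dNL (-1.61 nt over 26, -3.42 nt over 58 and -4.73 nt over the 82 genes), and depth as part of the cause stays open in wild type of experiment 2 (-1.35 nt over 356 genes with no more counts, which also differ in expression). A difference between experiments cannot be told apart either, since wild type of experiment 1, grown in the experiment of pcf11-13, had -4.14 nt (-4.69 to -3.88) but depth is open in that pair. Effects of the allele, of its missing tag, and of mating type or strain background may each account for the 1.35 nt. They cannot be told apart, because the design joins them in 1 strain.

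The proximal measure responded differently to caffeine in 1 gene in pcf11-13 and in 122 genes in pcf11-dNL by limma, and in 0 and 0 genes with the experiment as a block or with the edgeR test of class counts.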

How the results depend on the processing

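Tests chosen after the results were seen were those with the controls of 1 experiment, the class-count tests, the additive caffeine term of the poly(A) measures, all alternatives of the poly(A) response differences, the medians over genes with matched counts or no more counts after caffeine, the untreated levels over genes chosen in pcf11-dNL, and the thinned and plasmid-free fits. Under the listed alternatives no named gene with a call reversed. Counts and library medians were judged only by whether they moved beyond set bounds. Among genes with no more raw counts after caffeine, the median change of the truncated share turned from -1.54 and -0.498 to 1.25 and 1.37 points in wild type and from -0.672 to 1.12 in pcf11-dNL, and that of length in wild type of experiment 1 from -4.14 to 0.139 nt. With the experiment as a block the direction of 15 list results turned, 8 from higher to lower and 7 from lower to higher. Of these, 4 had a call either without or with the block, all turned from higher to lower: heat shock in pcf11-dNL (camera adjusted p = 0.0019 without and 0.55 with the block) and between the mutants (0.00015 and 0.66), and the respiratory chain in pcf11-dNL (0.16 and 0.016) and between the mutants (0.016 and 0.20). The caffeine count in wild type, 1849, was between 1422 (DESeq2) and 2219 (additive term) with all 8 libraries, and 1495 with libraries thinned. Other size factors and no filter on low counts left all 6 expression counts within 1.5 times. Where a value below moved, the cause was not tested.

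Without 1 library each, counts ranged from 989 to 1759 for caffeine, 23 to 199 for pcf11-13, 0 to 1 for pcf11-dNL, 0 to 61 between the mutants, and 0 to 177 and 0 to 13 for the response differences in pcf11-13 and pcf11-dNL. For length they were 0 to 0 (caffeine), 0 to 240 (pcf11-13) and 0 to 2 (pcf11-dNL). For the truncated share they were 0 to 3 in pcf11-13. For the proximal measure they were 0 to 0 (caffeine), 0 to 70 (pcf11-13), 0 to 142 (pcf11-dNL), and 0 to 0 for both response differences. These fits assume that a lone library varies like the other groups, and the response differences could not be fitted without a mutant library.

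With the experiment as a replicate block, 30 genes passed in pcf11-13 and 8 between the mutants. For length, 0 passed with caffeine and 8 in pcf11-13, where VPS41, ORM1 and WSC3 kept their call among the 10 named genes. For the truncated share 0 passed in pcf11-13, and for the proximal measure 0 with caffeine, 0 in pcf11-13 and 0 and 0 for the response differences. The block took the call from 13 of the 20 named genes of pcf11-13, from HXT1 with caffeine and from AGA2 between the mutants, and apart from these and the list calls given above it changed no other call.

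DESeq2 called 763 genes in pcf11-13, 244 between the mutants, and 42 and 3 for the response differences in pcf11-13 and pcf11-dNL. A fit of 6 group means called 299 genes in pcf11-13 and 1 in pcf11-dNL. With the wild-type libraries of experiment 2 as the only controls, 9 genes passed in pcf11-13 and 0 between the mutants. With those of experiment 1, 18 passed in pcf11-13, 7 in pcf11-dNL and 2 between the mutants. With either set of controls 0 and 0 genes passed in pcf11-13 for each of length, truncated share and proximal measure.

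The caffeine count for length, 2, was 6 at a minimum of 10 counts, 16 at 50 counts, 0 on the log2 scale, 33 with a trend on the mean count and 71 as the additive term. The additive term for the truncated share called 544 genes. Transformed fractions gave 18 genes in pcf11-13 for the truncated share and 151 with caffeine for the proximal measure. The edgeR test of class counts gave 657 (caffeine) and 161 (pcf11-13) for the truncated share, and 194 and 29 for the proximal measure. For the proximal response difference in pcf11-13, 5 genes passed at 10 counts, 0 at 50 counts, 0 transformed and 0 with class counts. In pcf11-dNL it was 56 with a trend and 0 with class counts.

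At a minimum of 50 counts, median 3′ UTR lengths without and with caffeine were 140 and 131 nt in wild type of experiment 1, 138 and 130 nt in experiment 2, 145 and 132 nt in pcf11-dNL, and 140 nt in untreated pcf11-13. The truncated median of untreated pcf11-dNL was 6.05%. The proximal medians were 0.284% and 0.303%, 0.286% and 0.313%, 0.387% and 0.401%, and 0.406% and 0.386% in pcf11-13. By camera with an estimated correlation, 0 lists passed in each of the 6 comparisons, and by fry 0 (caffeine), 2 (pcf11-13), 0 (pcf11-dNL), 1 (between the mutants), 0 and 0 (response differences).

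Of the other alternatives, 156 values of counts and medians moved by less than the bounds and 72 by more. For single named genes, 861 values kept their side of the threshold, 150 lost a call and 4 gained one. In the tests with known changes, simulated 2-fold changes were recovered in 4% and 6% of genes for the response differences in pcf11-13 and pcf11-dNL, against 51% for caffeine in wild type and 40% for pcf11-dNL. The smallest libraries were untreated wild type of experiment 1 (1070278 counts) and untreated pcf11-dNL (1071339).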

Other observations

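The genes in this part were singled out, and the tests of plasmid counts were chosen, after the values were seen, while the counts of splits were planned. NRD1 and CBP1 belong to the listed genes whose own early poly(A) sites are known, and their values stood apart in pcf11-13. Neither response difference passed when adjusted over all tested genes, nor did that list as a whole (camera adjusted p = 0.24). NRD1 stood at 306 and 40.9 CPM without and with caffeine in wild type of experiment 1, 193 and 32.4 in experiment 2 and 254 and 47.95 in pcf11-dNL, but at 120 and 142 in pcf11-13 (response difference 3.00 ± 0.49, edgeR adjusted p = 0.158). CBP1 (YJL209W, chromosome X, 38005 to 39969), which encodes a mitochondrial protein that stabilises cytochrome b mRNA, stood between 58.8 and 104 CPM in 7 libraries and at 479 in treated pcf11-13. Its difference of the caffeine response was 2.70 ± 0.40 on the log2 scale (edgeR adjusted p = 0.14). The truncated share of CBP1 went with caffeine from 33.3% to 60.1% and from 22.7% to 47.0% in wild type, from 31.1% to 59.2% in pcf11-dNL, and from 42.8% to 12.6% in pcf11-13. That of HRP1, another factor of 3′ end formation, went from 66.6% to 81.3%, 74.7% to 77.1%, 74.4% to 84.2% and 68.9% to 45.6% in the same order. DEF1 had a lower share with caffeine in all 4 pairs, with 24.8% in pcf11-13 and 28.7% in pcf11-dNL after treatment. None of these shares passed by limma.

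Other genes stood apart in single strains or experiments. GPG1, a subunit gene linked to G-protein signalling, rose with caffeine in wild type by 4.25 ± 0.35 (edgeR adjusted p = 0.000868), from 5.95 and 9.80 CPM to 128 and 185. In pcf11-13 it stood at 52.5 and 58.7 CPM (response difference -4.09 ± 0.53, edgeR adjusted p = 0.14). EGO4 stood at 493 CPM in untreated pcf11-dNL against 55.1 after caffeine, 38.7 to 47.1 in wild type, and 143 and 157 in pcf11-13 (response difference in pcf11-dNL -3.22 ± 0.39, edgeR adjusted p = 0.178). The copper metallothionein gene CUP1-1, which lies in a repeated array, stood between 897 and 1702 CPM in the 4 libraries of experiment 1 and between 4786 and 8265 in those of experiment 2.

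Both wild-type libraries of experiment 1 had high counts of URA3 (18920 and 40850 CPM against 69.3 to 247 elsewhere) and of 2-micron features, together 8.36% and 11.4% of the counts. The genes POL4, SIR4, UTR1 and CYC1 were also higher there than in experiment 2, by 7.92, 4.60, 4.57 and 2.58 on the log2 scale without caffeine. PCF11 was higher there by 0.91 without and by 0.27 with caffeine. Tables argued against library depth, since the equally deep treated library of experiment 2 had 0.304%. The neighbours of URA3, GEA2 and TIM9, differed by at most 0.38 between the experiments, which is consistent with extra plasmid copies of URA3 rather than of the chromosomal region, as a hypothesis. Without the 2-micron features, URA3, POL4, SIR4, UTR1 and CYC1, 1883 genes passed for caffeine in wild type and 191 for pcf11-13. No biological explanation was tested.

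The additive fit of genotype and medium was repeated on the 34 splits of the 8 libraries into 4 and 4 that could be fitted, the real one included. For expression, the real caffeine term called 2219 genes and the highest other split 3, so that 1 of 34 was as large. For length it called 71 against 0 (1 of 34) and for the truncated share 544 against 9 (1 of 34). These counts cannot decide on chance. Most splits do not part every pair of an untreated and a treated library. A split other than the real one also leaves caffeine effects in the residual spread. For the proximal measure it called 2 against 13, with 3 splits as large, and chance cannot be excluded. Splits that part all 4 pairs of an untreated and a treated library numbered 8, too few to exclude chance by themselves. Among these the highest other split called 0 genes for expression, 0 for length, 1 for the truncated share and 1 for the proximal measure.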
